A study of Mus musculus with 25 samples.

How the data were processed

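Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on V6.5 cells, a mouse embryonic stem (ES) cell line grown on feeder fibroblasts and passaged off the feeders before harvest. The targets were the transcription factors Oct4, Sox2, Nanog and Tcf3, the Polycomb subunit Suz12, and the histone marks H3K4me3, H3K79me2 and H3K36me3. Whole cell extract (WCE) served as input. Samples were grouped by the target named in their titles, which gave 19 libraries in 9 groups. Several titles give no plain replicate number, and the numbers used for them were assigned here: replicate 4 of H3K4me3, replicate 1 of Suz12, and both libraries of H3K79me2 and of H3K36me3, whose titles can be read as parts a and b of replicate 1. The H3K36me3 libraries differed by more than sampling noise (chi-square per degree of freedom 1.90) and were counted as 2 samples. The series also has 6 small RNA samples, which are not analysed here. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

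Per the labels' protocols, chromatin was sonicated and immunoprecipitated, and the recovered DNA was ligated to adapters, amplified by PCR and size selected on a gel before sequencing. The deposited values are counts: each line pairs a read sequence with the number of times that sequence was read, with no position and no gene. An aligner and a genome build are not given in the sources used here, and no reference genome was used here. Reads were therefore not placed on chromosomes. Genome windows, promoters, gene lists and distance profiles, which had been planned, are not analysed here, and every value below belongs to a sequence rather than to a coordinate.

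The planned test assumed a signal in windows and used limma. Since the files hold counts, the same comparisons were made with the quasi-likelihood F test of edgeR 4.0.16 under R 4.3.3, as the plan foresaw for that case. Features changed from windows to short sequences. Libraries were scaled to their number of usable reads, as planned for windows, and trimmed mean of M values (TMM) scaling was run as an alternative although the plan had named it for counts. All groups share 1 estimate of the spread. Benjamini-Hochberg (BH) adjustment was applied over all features of a comparison, and a call needs an adjusted p under 0.05 together with a log2 fold of at least 1. Motif and repeat comparisons are called on the adjusted p alone, and their sizes are given. Standard errors (SE) are the absolute log2 fold divided by the square root of F.

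Reads were 26 bases long, except in Suz12 replicate 1, H3K79me2 replicate 1 and H3K36me3 replicate 1, where they were 22 bases long and matched bases 2 to 23 of a longer read. Bases 2 to 23 were used in every library. Reads with an unread base were left out, as were reads matching either of 2 adapter sequences with up to 2 mismatches over 11 bases, and reads in which at most 2 kinds of dinucleotide made up at least 80% of the overlapping dinucleotides. This left 848927 to 12328023 usable reads per library from 919240 to 12798241 listed. RPM below stands for reads scaled to the usable reads of a library. Sequencing reads amplified by PCR carry no molecular identifiers, so counting intervals and the counting floor cover counting error only.

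The libraries numbered H3K4me3 replicate 4 and H3K79me2 replicate 1 here list 919240 reads each, and their 848927 usable reads, with 765463 distinct sequences, are the same over the bases used, with identical counts. Both were left out of the main comparisons. The Tcf3 runs differed by less than sampling noise (chi-square per degree of freedom 0.984, p = 0.98), whereas the Sox2, Nanog and Suz12 pairs gave 1.29, 1.04 and 2.32. The Tcf3 runs were summed and counted as 1 sample. The main comparisons used 16 libraries: Oct4, Tcf3 and H3K79me2 had 1 library each, Sox2, Nanog, Suz12, H3K36me3 and input had 2, and H3K4me3 had 3, which leaves 7 residual degrees of freedom. Groups with 1 library are assumed to vary like the others and have no replicate check of their own.

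All 8-base sequences (8-mers, both strands combined) were counted, and 32852 were tested after leaving out those of the adapters. Reads were searched for 20 binding motifs, of which 19 were chosen before the motif counts were made and the POU palindrome ATGCGCAT was added after the 8-mers had been seen. Each motif was set against the summed reads of up to 20 permutations of its own letters with the same number of CpG dinucleotides (389 in all, 9 for Sp1). This is meant to lessen effects of base composition but need not cancel them, since frequent permutations weigh most in the sum. BH adjustment ran over the 20 motifs. The composite Oct-Sox motif allowed 2 mismatches. Reads were also matched by short exact words to 7 repeat families, whose consensus sequences were written from general knowledge and checked against the input reads.

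Last, reads of 1 target were chained into contigs through overlapping 18-base words found in at least 3 and at most 18 distinct 26-base reads, keeping contigs of at least 37 bases. Libraries of 22-base reads therefore built no contigs, and those of Suz12 come from its replicate 2 alone. To leave out repeats, words seen in H3K36me3 or H3K79me2 reads were dropped from contigs of the 4 factors, and words seen at least 2 times in Nanog or Tcf3 reads were dropped from contigs of Suz12 and H3K4me3. This mask takes out every such word, whether or not it comes from a repeat. The target that chose a contig and the groups that masked it stayed out of its tests, so the tested libraries had no part in chaining the contigs, although some had a part in the filters described next. Contigs with under 0.5 RPM on average over the 16 libraries were not tested. That average includes the tested libraries, which raises the share of tested contigs that are called. From the Suz12 set, 42 contigs with at least 10 reads in Oct4, 10 in H3K79me2 replicate 2 and 5 in H3K36me3 replicate 2 were set aside after their levels had been seen, with 1 H3K4me3 contig that shared a word with them. Levels and calls of Suz12 contigs in those 3 libraries are therefore not free of selection. Levels relative to input over a whole contig set are sums over all its contigs, tested or not, except those whose mean input was over 10 times the median of contigs with input reads. Neighbouring contigs can come from 1 bound region and are not independent.

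The rule for named items was fixed for regions. Its part for the 4 factors was carried over to contigs: the 5 contigs with the highest fold in the least enriched of the other factors, among contigs called in all of them, with every tested library above every input library and input set to no less than 3 reads over both libraries. The parts for single targets and for the longest Suz12 regions need merged windows and were not applied; the 8-mers with the highest folds are named instead. Ratios at single contigs have exact Poisson 95% intervals.

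The fits were tested on simulated counts with 200 features changed. With a log2 change of 1.5 in 8-mers, 200 of 200 were recovered for Sox2 and for Oct4 with 0 false calls. On Nanog contigs (1744 tested), a log2 change of 4 was recovered in 85% for Sox2 and 63.5% for Oct4, and a log2 change of 2 in 29% and 4.5%, with at most 5 false calls. Rises and losses were simulated in equal number, with an assumed dispersion. For contigs, input was given the mean level of the fitted libraries, whereas most real contigs hold few input reads. The percentages are therefore not the power to find enriched contigs, and reads per contig were not varied.

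Sample groups, the list of comparisons, thresholds and most alternatives were fixed before the data were examined. That list held Tcf3 against the mean of Oct4, Sox2 and Nanog, but not the contrasts of those factors with each other. Several choices followed results: the second adapter sequence was added after the Suz12 8-mers were seen, the low-count filter for contigs and the dispersion trend of DESeq2 1.42.0 were changed after their counts were seen, and H3K4me3 contigs were split by Suz12 reads after a split by calls had been tried. The contig approach as a whole was devised after the files turned out to hold unplaced reads, and an earlier build of contigs was replaced. The alternatives tried were DESeq2, other scalings, no filter, a fold threshold inside the test, single-comparison fits, a replicate block, distinct sequences counted once, all 19 libraries as labelled, the H3K36me3 libraries summed as 1 sample, and each library left out in turn. Counting and contig building used Python 3.11.15 with numpy 2.4.6, numba 0.67.0, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.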

Results

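ChIP-seq reads from V6.5 mouse ES cells were compared with reads of whole cell extract to ask which sequences each protein or histone mark was enriched on, whether the 4 transcription factors Oct4, Sox2, Nanog and Tcf3 were enriched on the same sequences, and how Suz12, H3K79me2 and H3K36me3 were distributed over sequences carrying H3K4me3. Oct4, Sox2 and Nanog are regulators of the pluripotent state, and Tcf3 is a DNA-binding protein of the Wnt pathway. Suz12 belongs to the Polycomb complex that methylates H3K27. H3K4me3 marks promoters, and H3K79me2 and H3K36me3 mark transcribed genes.

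The deepest libraries were Sox2 replicates 1 and 2 with 12798241 and 12639551 reads. Oct4 had 8763614 reads, Nanog 8927251 and 8874819, Tcf3 7774013 and 8039078, Suz12 3194637 and 7542731, and input 5019381 and 6227312. H3K4me3 replicates 1 to 3 had 2818366, 3732335 and 4373720 reads, H3K79me2 replicate 2 had 5917433, and H3K36me3 had 2003183 and 7427332. A further list titled as H3K4me3, numbered replicate 4 here, had the same 848927 usable reads over the bases used as the list numbered H3K79me2 replicate 1, out of 919240 listed in each, and both were left out of the main comparisons. The Tcf3 runs differed by less than the sampling noise and were counted as 1 sample. Oct4, Tcf3 and H3K79me2 therefore have no replicates in what follows. The titles of the H3K36me3 libraries can be read as parts a and b of replicate 1, so their n of 2 counts samples that may not be separate replicates. The Nanog libraries shared rarely listed sequences nearly as often as the Tcf3 runs did, so the n of 2 for Nanog may count runs of 1 library. Single contigs and rare sequences in the Suz12 replicate 1 and H3K36me3 replicate 1 libraries rest on few reads.

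The composite Oct-Sox motif, the joined recognition sequence of Oct4 and Sox2, was the most enriched of the 20 motifs in Oct4 and in Sox2 reads. Relative to its permuted controls, its log2 fold over input was 2.87 in Oct4 (SE 0.13, n = 1) and 2.39 in Sox2 (SE 0.11, n = 2). It was also enriched in Nanog, at 1.19 (SE 0.12, n = 2), and in Tcf3, at 0.72 (SE 0.14, n = 1), and not in Suz12, at -0.03 (SE 0.15, n = 2). The composite motif was found at 262 RPM (reads scaled to library size) in Oct4, 213 in Sox2, 88.2 in Nanog, 57.8 in Tcf3 and 31.4 in input. All 20 permuted controls lay below the motif in each of the 4 factors. The adjusted p of edgeR's quasi-likelihood test was 3.4e-09 for Oct4, 7.8e-09 for Sox2, 2.1e-05 for Nanog and 0.0022 for Tcf3.

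The parts of the composite motif differed between some of the factors. The octamer ATGCAAAT, bound by Oct4 and other POU factors, had a log2 fold over controls of 1.41 in Oct4 (SE 0.066), against 0.41 in Sox2, 0.39 in Nanog and 0.31 in Tcf3 (SE 0.056, 0.057 and 0.068). The Sox motif CATTGTT was highest in Sox2, at 0.66 (SE 0.052), followed by Nanog at 0.35 (SE 0.052) and Oct4 at 0.31 (SE 0.062), and Tcf3 gave 0.01 (SE 0.063). Nanog minus Sox2 was -0.03 at the octamer (adjusted p 0.72) and Oct4 minus Nanog -0.04 at the Sox motif (adjusted p 0.77), neither past the test. In Oct4 1 of the 20 Sox controls lay above the motif. The TCF motif had smaller values in Oct4, at 0.08 (SE 0.026), above 14 of its 20 controls, and in Sox2, at 0.03 (SE 0.022), above 7. The TCF motif rose in Tcf3, by 0.17 (SE 0.026, adjusted p 0.0012), above all 20 controls, and in Nanog, by 0.15 (SE 0.022), above 18 of them. The short homeobox pattern TAATKK passed the test in Oct4 at 0.06 (adjusted p 0.038), in Sox2 at 0.08 (adjusted p 0.0036) and in Nanog at 0.06 (adjusted p 0.023), with 4, 2 and 4 of its 20 controls above it, and gave 0.00 in Tcf3 (adjusted p 0.95).

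A POU palindrome, ATGCGCAT, had a log2 fold over controls of 2.41 in Oct4 (SE 0.14). It had been added as a motif because it was the highest 8-mer in Oct4, so its place above its controls there follows from that choice and is no independent test. It was found at 353 RPM in Oct4 and 82.7 in input. In Sox2 the value was 0.60 (SE 0.12), but 9 of 20 controls lay above it, so base composition cannot be set aside there. Taken singly, the controls had a median log2 fold over input of 0.148 in Oct4 and 0.278 in Sox2. The palindrome itself, without controls, had 2.09 and 0.322. The motif of Esrrb, an orphan nuclear receptor of ES cells, rose in Oct4 by 0.49 (SE 0.095), above all 20 controls. In Nanog its value was 0.39 (SE 0.080), and 1 of the 20 controls lay above it, at 0.46. The motif of CTCF, an insulator protein, was higher in Oct4, at 0.69 (SE 0.077), and lower in Nanog, at -0.55 (SE 0.066), and in Tcf3, at -0.42 (SE 0.080), than in input. Of the 389 permuted controls taken as motifs themselves, 1 passed both thresholds in Oct4, 2 in Sox2 and 0 in Nanog, Tcf3 and Suz12, 1 in H3K36me3, and 24 in H3K4me3 and 25 in H3K79me2, so motif folds over input in the last pair are not reported. In H3K36me3 none of the 20 motifs lay above all of its controls, and the Ets motif was lower than in input and below all 20 controls, at -0.64 (SE 0.16, adjusted p 0.014). The Sp1, Stat and NFY motifs were also lower and below all of their controls, at -0.50 (adjusted p 0.014), -0.28 (adjusted p 0.017) and -0.18 (adjusted p 0.0040).

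**Figure D1:**
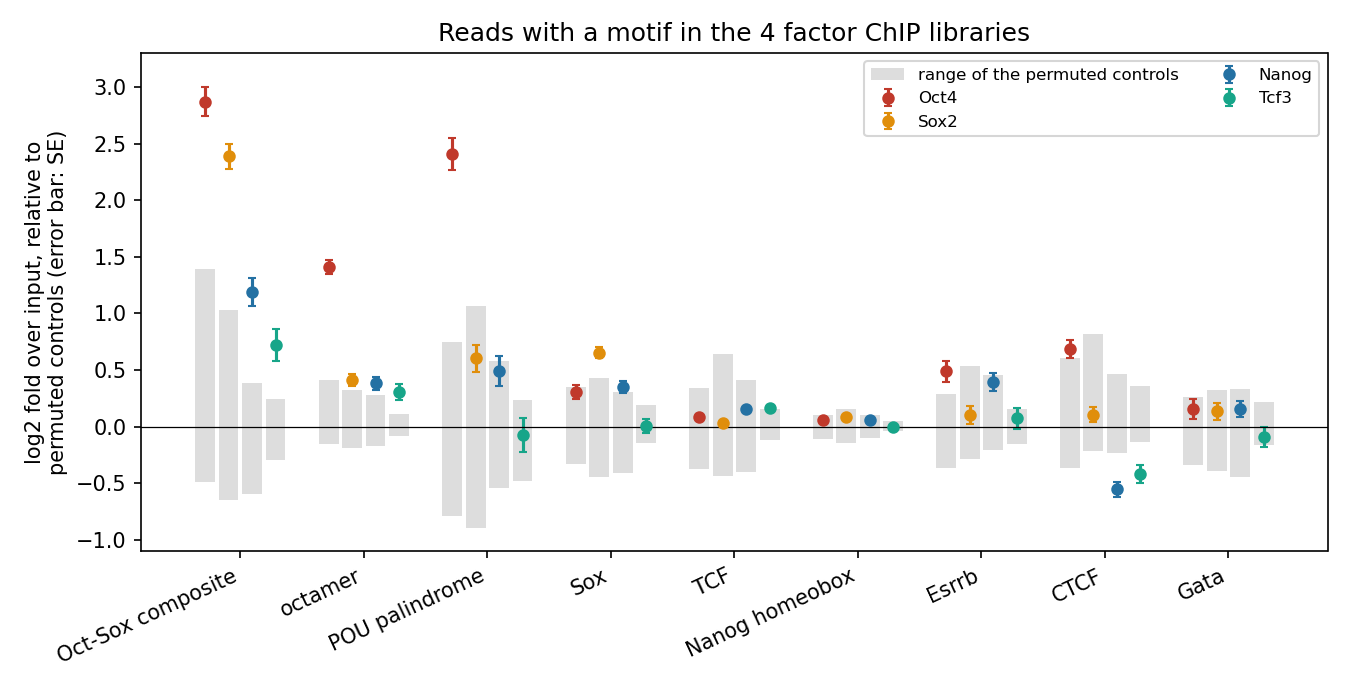
Log2 fold over input of reads with each motif, relative to the motif's permuted controls (y axis), for 9 motifs (x axis) in Oct4, Sox2, Nanog and Tcf3; points are edgeR estimates, error bars are SE and grey bars span the controls. The composite Oct-Sox motif lies above its controls in all 4 factors, from 2.87 in Oct4 to 0.72 in Tcf3, and the POU palindrome, chosen from the Oct4 8-mers, stands at 2.41 in Oct4.

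Tcf3 was tested directly against the mean of the other factors. The composite motif was lower in Tcf3 by a log2 difference of -1.43 (SE 0.11, adjusted p 1.5e-06), the POU palindrome, chosen for its level in Oct4, by -1.24 (SE 0.13), and the octamer and Sox motifs by -0.43 each (SE 0.063 and 0.058). The TCF motif differed by 0.08 (SE 0.024, adjusted p 0.021), with 2 of 20 controls above it. Within the other 3 factors, Oct4 exceeded Sox2 by 0.99 at the octamer (SE 0.066, adjusted p 2.3e-07) and Sox2 exceeded Oct4 at the Sox motif, the difference Oct4 minus Sox2 being -0.35 (SE 0.064, adjusted p 0.00083).

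The 8-mers most enriched in Oct4 were POU sequences. In Oct4, 53 of 32852 8-mers passed both thresholds, 34 of them with CpG, led by ATGCGCAT at a log2 fold of 2.10 (SE 0.13, adjusted p 3.5e-06), ATGCTAAT at 1.65 (SE 0.056) and the octamer at 1.51 (SE 0.055). In Sox2, 52 were higher and 12 lower, led by the Sox-like AACAATAG at 1.52 (SE 0.082, adjusted p 1.9e-06). In Nanog 3 were higher, led by the homeobox-like CTAATTAG at 1.16 (SE 0.091, adjusted p 4.3e-05), and CTAATTAG was also high in Sox2, at 1.32 (SE 0.091). In Tcf3 edgeR called 0, with 0 higher and 1 lower at an unadjusted p under 0.05 and the same fold, and DESeq2 called 0 higher. The difference between Tcf3 and the mean of the other factors gave 0 calls in edgeR, 0 at an unadjusted p under 0.05 and the same fold, and 0 in DESeq2.

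These counts depended on which input library was kept. Without input replicate 2 they were 111 for Oct4, 168 for Sox2 and 8 for Nanog, and without input replicate 1 they were 29, 32 and 1. With TMM scaling they were 31 for Oct4 and 24 for Sox2, and with the fold threshold inside edgeR's test 6 for Oct4 and 0 for Sox2 and Nanog, where 11 and 1 passed at an unadjusted p under 0.05, and DESeq2 called 40 and 4. When each 8-mer was compared only with 8-mers of the same GC and CpG content, edgeR called 17 in Oct4, 4 in Sox2 and 0 in Nanog, the last also 0 at an unadjusted p under 0.05 with the same fold. In that comparison ATGCGCAT had a log2 fold of 2.03 in Oct4, AACAATAG 1.22 in Sox2 and CTAATTAG 0.95 in Nanog.

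Each of the 4 factors was enriched over input on the contigs built from each other factor, taken as a set. Contigs built from reads of 1 factor were tested in the other factors, whose reads had no part in building them. Over the contigs built from Nanog reads, Oct4 had 23.4 times the input level (n = 1), Sox2 13.2 ± 0.57 (SD, n = 2) and Tcf3 12.0 (n = 1), whereas Suz12 had 0.91 ± 0.11 (n = 2) and H3K4me3 0.868 ± 0.05 (n = 3). Words seen in H3K79me2 or H3K36me3 reads had been dropped from the contigs of all 4 factors. The low H3K4me3 level may be in part set by that mask, so it does not show that the factors' sequences lack H3K4me3. Contigs built from Oct4 reads gave 16.8 ± 0.64 for Sox2, 19.7 ± 0.57 for Nanog and 10.5 for Tcf3. Contigs built from Sox2 reads gave 31.0 for Oct4, 22.9 ± 0.42 for Nanog and 9.40 for Tcf3, and those built from Tcf3 reads gave 20.9 for Oct4, 9.35 ± 0.3 for Sox2 and 21.4 ± 0.49 for Nanog.

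**Figure D2:**
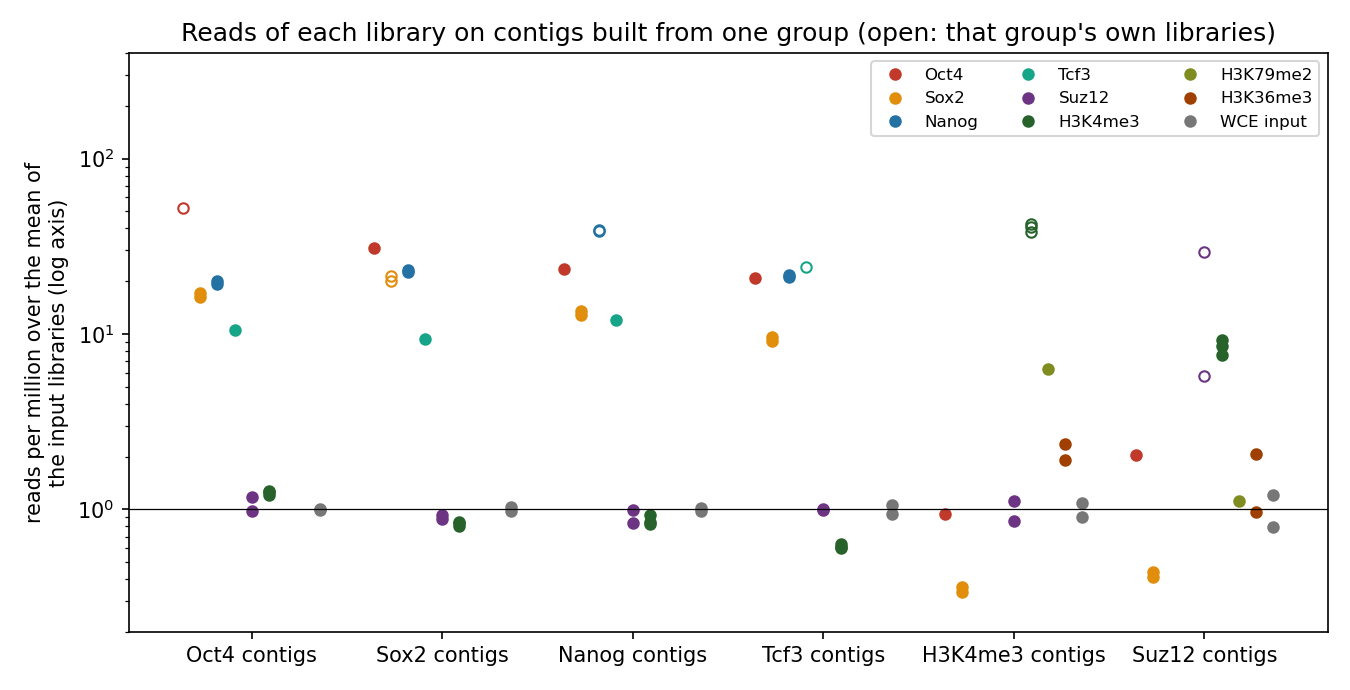
RPM of each library over the mean of both input libraries (log y axis), summed over contigs built from the group on the x axis; each point is a library and open points are the libraries that built the contigs. On the contigs of the 4 factors the other factors lie between 9.13 and 31.0 times input, and Suz12 and H3K4me3 lie between 0.602 and 1.28. Words seen in H3K36me3 or H3K79me2 reads had been dropped from these contigs, which may lower H3K4me3.

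Of 1744 Nanog contigs that passed the low-count filter, edgeR called 1505 (86.3%) in Oct4, 1471 (84.3%) in Sox2 and 1148 (65.8%) in Tcf3, and 996 in all 3 together. The tested libraries count toward that filter. Without it 3184, 2326 and 1377 of the 5750 contigs built were called, and 863 in all 3. Independent lists of the filtered sizes would share 836, and unchanged groups simulated against the same input libraries shared at most 0 in 10 simulations, which does not measure how far shared input raises the overlap of real calls. Part of the excess may come from the shared input libraries, which were not split because each part would hold 1 library, and the size of that part was not measured. The count in all 3 was 554 without input replicate 2, 587 without Sox2 replicate 1 and 560 without Sox2 replicate 2, and the Tcf3 count was 751 without input replicate 2. With DESeq2 the counts were 700, 536, 244 and 185. In Suz12 edgeR called 0 Nanog contigs, with 38 at an unadjusted p under 0.05, DESeq2 called 0, with 21, and edgeR called 20 without Suz12 replicate 1. In H3K4me3 7 were called and 45 were lower than input, on contigs that had lost the words seen in H3K79me2 or H3K36me3 reads. Lower than input were also 39 of the Nanog contigs in Oct4, 46 in Sox2 and 40 in Tcf3, and 0 in Suz12.

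The contigs of the other factors were also called in most cases after the same filter. Of 923 Oct4 contigs, 810 were called in Sox2, 785 in Nanog and 516 in Tcf3, and without the filter 1714, 1504 and 730 of the 2498 built. Of 1263 Sox2 contigs, 1154 were called in Oct4, 1138 in Nanog and 688 in Tcf3, and of 499 Tcf3 contigs 451 were called in Oct4, 391 in Sox2 and 443 in Nanog. On the Oct4 contigs 22 were called in Suz12, and 0 of those were among the Nanog calls, where independent lists would share 18.7. The contigs set aside from the Suz12 set had a like pattern, at 321 RPM in Oct4, 231 and 1031 in Suz12 replicates 1 and 2, and 1.12 and 1.24 in Nanog. They had been picked in part by their Oct4 reads, and words seen at least 2 times in Nanog or Tcf3 reads had been dropped from them. The likeness in Oct4 and Nanog therefore follows in part from those choices. The 22 may come from the same unidentified source, which was not tested. That 0 Oct4 contigs shared a word with those set aside cannot decide it. Words seen in H3K36me3 or H3K79me2 reads had been dropped from Oct4 contigs, and those set aside were picked for reads in these marks.

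The contigs also carried the octamer, composite and TCF motifs. The octamer was found in 7.17% of 2498 Oct4 contigs, against a median of 0.12% for its controls, in 4.4% of Sox2, 3.06% of Tcf3 and 1.86% of Nanog contigs. The composite motif was found in 2.40% of Oct4 and 2.39% of Sox2 contigs, and in 0.365% of Nanog and 0.612% of Tcf3 contigs. The TCF motif was found in 14.1% of 1143 Tcf3 contigs, where the highest control reached 7.61%, and in 4.05% of 5750 Nanog contigs. The homeobox pattern TAATKK was found in 14.2% of Nanog contigs, above 18 of its 20 controls, the highest of which reached 20.2%. In Oct4, Sox2 and Tcf3 contigs it lay above 13, 16 and 13 of them. Oct4 contigs with the composite motif had 2.41 and 2.37 times the Sox2 reads of those without it in the 2 Sox2 libraries, 1.03 and 0.994 times the Nanog reads, and 1.33 and 1.22 times the reads of input replicates 1 and 2. Sox2 contigs with the motif had 1.86 times the Oct4 reads 0.733 and 0.727 times the Nanog reads, and 0.862 and 1.12 times the input reads. These ratios were not tested.

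Named contigs were ranked by the fold in the least enriched of the other factors, with input set to no less than a floor of 3 reads over both input libraries. The first was built from Sox2 reads (Sox2_c750, 163 bases) and holds a composite motif with the 2 mismatches allowed. Both lie in its Sox part, which reads CTTTCTT in place of CATTGTT, and its octamer is exact. Its sequence is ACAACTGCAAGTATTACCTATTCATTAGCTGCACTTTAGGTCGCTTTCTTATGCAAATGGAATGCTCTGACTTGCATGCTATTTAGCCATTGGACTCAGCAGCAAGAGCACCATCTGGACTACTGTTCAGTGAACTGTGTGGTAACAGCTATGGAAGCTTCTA. It had 132 Oct4, 296 Nanog and 135 Tcf3 reads against 3 input reads, which is 55.1 times input for Oct4 (95% counting interval 18.5 to 271), 63.9 for Nanog (21.6 to 312) and 34.0 for Tcf3 (11.4 to 167). Tcf3_c107, a contig of 210 bases built from Tcf3 reads, had 182 Oct4, 365 Sox2 and 162 Nanog reads against 4 input reads, or 57.0 (21.9 to 212), 39.2 (15.2 to 145) and 26.2 (10 to 97.4) times input. Its sequence is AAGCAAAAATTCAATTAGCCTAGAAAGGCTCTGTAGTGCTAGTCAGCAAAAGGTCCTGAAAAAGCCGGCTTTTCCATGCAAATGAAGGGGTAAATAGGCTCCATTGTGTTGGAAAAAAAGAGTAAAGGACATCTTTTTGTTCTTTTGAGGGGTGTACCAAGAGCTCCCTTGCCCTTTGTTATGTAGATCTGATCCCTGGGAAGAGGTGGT. Oct4_c1095, with 199 bases and 0 input reads, stood at 27.9 times the floor in Sox2, 84.6 in Nanog and 30.5 in Tcf3. The lower ends of its 95% counting intervals over input put it at least 22.5-fold higher in Sox2, 68.5-fold in Nanog and 24.4-fold in Tcf3. Sox2_c209, with 144 bases and 1 input read, had 115 (20.2 to 4603) times input in Oct4, 201 (35.8 to 7952) in Nanog and 80.1 (14.1 to 3195) in Tcf3. Tcf3_c1006, with 165 bases and 2 input reads, had 91.5 (24.9 to 763) in Oct4, 39.1 (10.7 to 325) in Sox2 and 46.3 (12.6 to 386) in Nanog. Against the floor, the lowest folds of the last pair were 26.7 and 26.1. Their places in the genome were not determined here.

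The 8-mers enriched in Suz12 were mostly CpG sequences, although the reads as a whole were not richer in GC. Suz12 replicate 2 held 0.477 CpG per read and replicate 1 held 0.359, against 0.347 and 0.363 in the input libraries, and GC content was 44.5% and 43.7% against 45.6% and 45.5%. Of 469 8-mers higher in Suz12 than in input, 461 contained CpG, led by CGGCGCCG at a log2 fold of 1.97 (SE 0.28, adjusted p 0.00086, n = 2). The libraries differed in strength: 1091 8-mers were called without Suz12 replicate 1 and 49 without replicate 2. With the fold threshold inside its test edgeR called 0 in Suz12, with 162 at an unadjusted p under 0.05, and with all 19 libraries as labelled 0, with 146, whereas DESeq2 called 429. When compared within classes of equal GC and CpG content, edgeR called 0 8-mers, with 0 at an unadjusted p under 0.05 and the same fold. None of the 20 motifs lay above all of its controls in Suz12, and the Nrf1 motif was lower, at -1.21 (SE 0.16, adjusted p 0.00021). The Sp1, Klf and E-box CACGTG motifs were also lower and below all of their controls, at -0.617 (adjusted p 0.0018), -0.403 (adjusted p 0.00069) and -0.345 (adjusted p 0.00087).

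Contigs built from Suz12 reads were enriched for H3K4me3. They were CpG-rich, with 6.52 CpG per 100 bases and 59.3% GC, near the 7.5 and 63.2% of H3K4me3 contigs. No CpG-matched contigs without Suz12 were compared, so this enrichment cannot be told from H3K4me3 on CpG-rich sequence in general. Over 126 Suz12 contigs, H3K4me3 had 8.46 ± 0.84 times the input level (SD, n = 3), Oct4 2.03 (n = 1) and Sox2 0.425 ± 0.018 (n = 2). H3K79me2 had 1.12 (n = 1) and H3K36me3 had 2.06 in replicate 1 and 0.971 in replicate 2. Contigs with many reads in Oct4, H3K79me2 replicate 2 and H3K36me3 replicate 2 had been removed from this set, so low levels in those 3 libraries are in part set by that choice. Words seen at least 2 times in Nanog or Tcf3 reads had also been dropped, which may lower the Oct4 and Sox2 levels. Whether base composition lowers the Sox2 level on these contigs was not tested. These contigs were chained from 26-base reads, which only Suz12 replicate 2 holds, so its level of 29.5 times input follows from that choice. Suz12 replicate 1, with no part in chaining, had 5.79 times input. Of 34 contigs tested, 18 were called in H3K4me3 by edgeR, and DESeq2 called 0, with 0 at an unadjusted p under 0.05 and the same fold.

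H3K4me3 reads were dominated by CpG-rich sequence. Their GC content was 56.0 to 56.7% in replicates 1 to 3, against 45.6 and 45.5% in the input libraries, and they held 1.04 to 1.06 CpG per read against 0.347 and 0.363. Of 32852 8-mers, 6986 were higher than in input, 6739 of them with CpG, and 3113 were lower. The highest was CGCCGCCG at a log2 fold of 4.23 (SE 0.26, adjusted p 1.1e-08, n = 3). Within classes of equal GC and CpG content 166 were higher and 159 lower.

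On 52771 contigs built from H3K4me3 reads, H3K79me2 had 6.34 times the input level (n = 1) and H3K36me3 2.13 ± 0.33 (SD, n = 2). Suz12 had 0.989 ± 0.19 (n = 2), Oct4 0.94 (n = 1) and Sox2 0.35 ± 0.014 (n = 2). Words seen at least 2 times in Nanog or Tcf3 reads had been dropped from these contigs. The Oct4 and Sox2 levels may be in part set by that mask, since Oct4 and Sox2 were high on contigs of Nanog and Tcf3. Sox2 reads also held less GC than input, 42.73 and 42.41% against 45.65 and 45.55%, and these contigs held 63.2%. Whether base composition lowers the Sox2 level was not tested. Of 14720 contigs tested, edgeR called 1924 in H3K79me2, 565 in H3K36me3 and 5 in Suz12. The H3K79me2 count was 208 without input replicate 2 and 413 without input replicate 1. The H3K36me3 count was 130 without input replicate 2, 206 without input replicate 1, 204 without H3K36me3 replicate 1, 143 without its replicate 2 and 261 with both summed as 1 sample. The Suz12 count was 0 without input replicate 2, Suz12 replicate 2, or either H3K36me3 library, 0 with the H3K36me3 libraries summed, with 95 at an unadjusted p under 0.05, 1 without input replicate 1 and 8 without Suz12 replicate 1. DESeq2 called 0 in each of the 3, with 0 in H3K79me2, 1 in H3K36me3 and 0 in Suz12 at an unadjusted p under 0.05 and the same fold.

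H3K4me3 contigs with Suz12 reads carried less H3K79me2 than others of the same CpG content. On 522 contigs with at least 5 Suz12 reads and at most 2 input reads, H3K79me2 stood at 4.72% of the H3K4me3 level, and on 10420 contigs with no Suz12 read, matched for CpG, at 14.3%. The ratio was 0.33 (95% counting interval 0.296 to 0.368, n = 1). For H3K36me3 the ratios were 1.08 (0.886 to 1.31) in replicate 1 and 1.06 (0.949 to 1.19) in replicate 2. A 2-sided permutation test over contigs gave p = 1e-05 for H3K79me2, the smallest that 100000 permutations can give, with a BH adjusted p of 3e-05 over the 3 libraries, and p = 0.7 for each H3K36me3 library. The H3K36me3 ratios changed with the limit on input reads and with the CpG matching. With any number of input reads the ratios were 1.83 (1.64 to 2.04) and 1.87 (1.75 to 1.99) for H3K36me3 and 0.518 (0.484 to 0.554) for H3K79me2, and with no CpG matching they were 0.854 (0.700 to 1.03) and 0.822 (0.734 to 0.918) for H3K36me3. No direction is therefore given for H3K36me3. With at least 3 Suz12 reads the H3K79me2 ratio was 0.554 (0.532 to 0.576). Contigs are not independent, since several can lie in 1 promoter, and H3K79me2 is a single library, so the test describes these libraries. Using Suz12 replicate 1 alone left 2 contigs with 1 H3K79me2 read and a ratio of 0.065 (interval 0.00165 to 0.362), and the H3K36me3 ratios were then 0.384 and 0.18, from 1 and 2 reads (intervals 0.00972 to 2.14 and 0.0218 to 0.649).

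**Figure D3:**
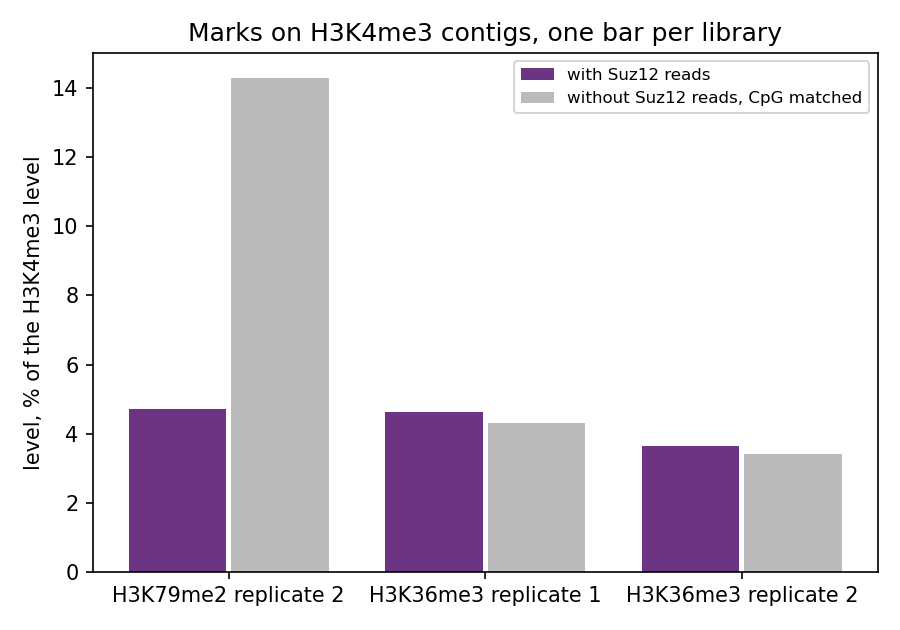
Level of H3K79me2 and H3K36me3 as a percentage of the H3K4me3 level (y axis) on H3K4me3 contigs with at least 5 Suz12 reads and on CpG-matched contigs without Suz12 reads, both with at most 2 input reads, with 1 bar per library and class. The H3K79me2 bars stand at 4.72% and 14.3%, and the H3K36me3 bars at 4.64% and 4.30% in replicate 1 and 3.63% and 3.42% in replicate 2, where the ratios become 1.83 and 1.87 without the limit on input reads.

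More H3K4me3 contigs had at least 5 Suz12 reads than had at least 5 input reads, 635 against 226 at 9621543 and 10448619 usable reads, although the level of Suz12 over the whole set was 0.989 times input. Relative to H3K4me3, Oct4 stood at 3.06% on the 522 contigs with Suz12 reads and 2.22% on the matched contigs, and Sox2 at 0.703% and 0.685% in replicate 1 and 0.836% and 0.723% in replicate 2. These differences were not tested.

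In H3K36me3 10 8-mers were higher than in input, all with CpG, and 4 lower, led by GCGACTTA at a log2 fold of 1.85 (SE 0.13, adjusted p 5.9e-05, n = 2). With each sequence counted once edgeR called 0 higher in H3K36me3, with 0 at an unadjusted p under 0.05 and the same fold, and with the fold threshold inside its test 0, with 8, whereas DESeq2 called 9. With all 19 libraries as labelled 4 were called. In H3K79me2 4 were higher and 257 lower, the highest being AAAAAAAC at 1.17 (SE 0.3, adjusted p 0.022, n = 1). The H3K79me2 count of higher 8-mers was 1 with TMM scaling, 14 within classes of equal GC and CpG content and 3485 with all 19 libraries as labelled, which adds the list under a second label. It was 0 in edgeR with each sequence counted once, with 2 at an unadjusted p under 0.05, and 0 with the fold threshold inside the test, with 0, and DESeq2 called 3.

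Repeat families differed between the targets. Major satellite, the tandem repeat of mouse pericentromeres, made up 4.63% of input reads and 0.386% of H3K79me2 reads, a log2 change of -3.58 (SE 0.2, adjusted p 1.5e-08, n = 1). It was also lower in H3K4me3, at -1.83 (SE 0.12, adjusted p 8.8e-08, n = 3), and in H3K36me3, at -0.72 (SE 0.14, adjusted p 0.00057, n = 2). Smaller losses passed the test in Sox2 at -0.56 (adjusted p 0.0018), Nanog at -0.49 (adjusted p 0.0058), Oct4 at -0.525 (adjusted p 0.046) and Suz12 at -0.34 (adjusted p 0.040). Minor satellite, the repeat of centromeres, was lower in H3K79me2 at -3.71 (SE 0.34), in H3K4me3 at -2.49 (SE 0.21) and in H3K36me3 at -1.99 (SE 0.24), and higher in Sox2 at 0.58 (SE 0.22, adjusted p 0.023). Telomeric repeats were lower in H3K79me2 at -3.83 (SE 0.49, adjusted p 2.0e-05), in Sox2 at -2.01 (SE 0.31, adjusted p 7.1e-05), in Tcf3 at -1.17 (SE 0.38, adjusted p 0.040), in Nanog at -1.11 (SE 0.30, adjusted p 0.0058) and in H3K4me3 at -0.98 (SE 0.28, adjusted p 0.0048). The sizes depended on how reads were counted: with each sequence counted once, major satellite was -2.60 in H3K79me2 and -1.22 in H3K4me3, and minor satellite was -1.04 in H3K36me3. With all 19 libraries as labelled, major satellite in H3K79me2 was -2.01.

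The short interspersed elements SINE B1 and B2, which are common near genes, went the other way in the marks of transcribed genes. SINE B1 rose in H3K79me2 by a log2 change of 0.99 (SE 0.17, adjusted p 0.00017) and in H3K36me3 by 0.42 (SE 0.14, adjusted p 0.017), and SINE B2 by 0.77 (SE 0.15) and 0.49 (SE 0.13). With all 19 libraries as labelled, SINE B1 in H3K79me2 was 0.45 (adjusted p 0.24). SINE B1 was lower in Sox2, at -1.25 (SE 0.14, adjusted p 9.6e-06, n = 2), and by less in Nanog at -0.68 (adjusted p 0.0013), Suz12 at -0.62 (adjusted p 0.0040), Oct4 at -0.52 (adjusted p 0.046) and H3K4me3 at -0.47 (adjusted p 0.0043), while Tcf3, at -0.42, missed the threshold (adjusted p 0.080). SINE B2 was lower in H3K4me3 at -1.15 (SE 0.12), Sox2 at -0.96 (SE 0.13), Nanog at -0.74 (SE 0.13), Suz12 at -0.57 (SE 0.13) and Tcf3 at -0.56 (SE 0.16). Adjusted p-values are from edgeR over the 7 families of a comparison. Repeat folds, unlike motif folds, have no control for base composition. Sox2 reads held 42.73 and 42.41% GC, against 45.65 and 45.55% in input, and CA and GA repeats were also lower in Sox2, at -0.89 (SE 0.11) and -0.82 (SE 0.08). Effects of base composition on the repeat folds were therefore not set apart.

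**Figure D4:**
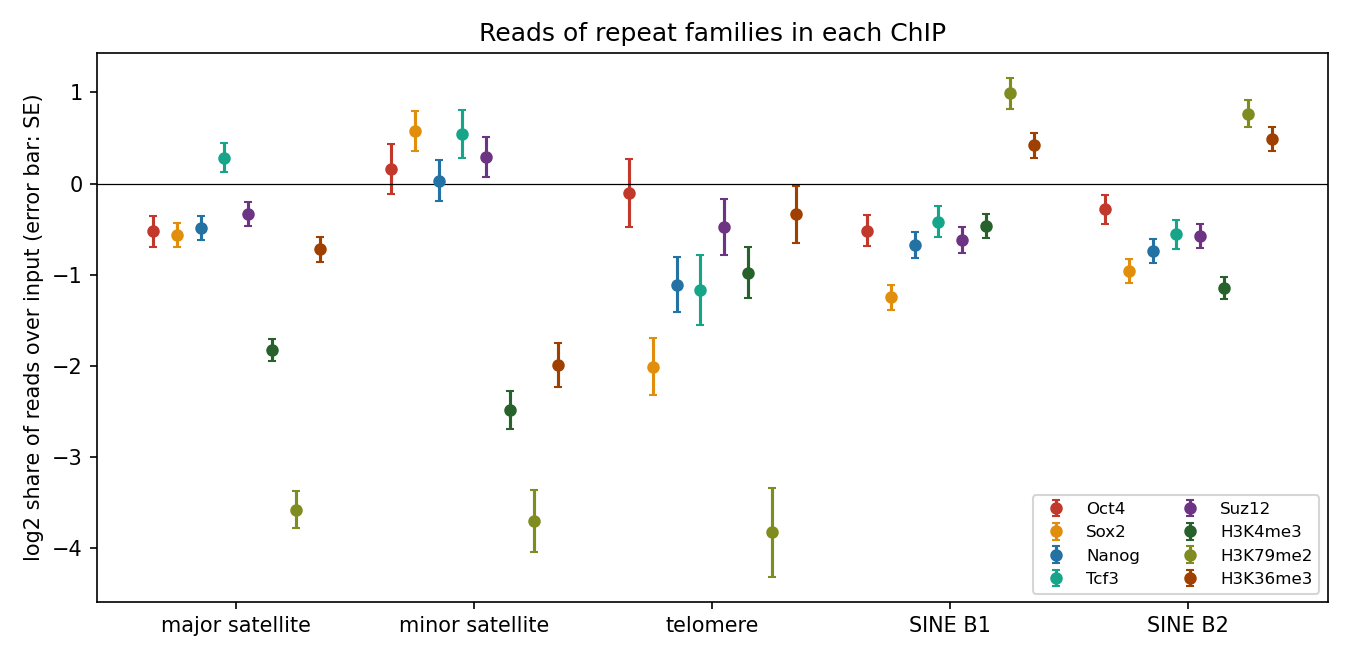
Log2 share of reads over input (y axis) for 5 repeat families (x axis) in each of the 8 targets; points are edgeR estimates and error bars are SE. H3K79me2 lies lowest at both satellites, at -3.58 and -3.71, and highest at SINE B1, at 0.99.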

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

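Of the tests in this part, only the share of ATGCGCAT reads in few sequence contexts was fixed before its result was seen, and all the others were chosen afterwards. Of the contrasts between factors, only Tcf3 against the mean of Oct4, Sox2 and Nanog was planned. Differences between Oct4, Sox2 and Nanog given below were not in the plan, and the palindrome was added after the 8-mers had been seen.

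One list of reads stands under the titles of an H3K4me3 library, numbered replicate 4 here, and of an H3K79me2 library, numbered replicate 1 here. On contigs built from the other H3K4me3 libraries its level was 34.0 times input, near the 37.9 to 42.2 of those libraries and far from the 6.34 of H3K79me2 replicate 2. Its log2 share of major satellite reads over input was -1.27, which is 2.32 above the -3.58 of H3K79me2 replicate 2. H3K4me3 replicates 1 to 3 gave -1.81, -1.78 and -1.90. Same-group libraries differed by at most 0.447. By that limit the list matched neither mark, though it lay nearer to H3K4me3, which argues against H3K79me2 reads. Its 8-mer counts differed from H3K4me3 replicates 1 to 3 by a chi-square per degree of freedom of 1.16, 1.25 and 1.13, and from every library of another target and input by 7.73 to 19.9, with 11.3 for H3K79me2 replicate 2, which argues for H3K4me3 reads under a second label among the kinds of sample compared here. As a library labelled H3K4me3 it also stood apart in low-complexity reads, with 2.05% against 0.252 to 0.327% in the other 3. H3K79me2 replicate 2 held 1.18%, so this value does not side with H3K4me3. For 1 measure, chance alone sets 1 sample apart in about 1 of 20 such groups. Several measures were checked, which makes such a flag more likely.

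The palindrome ATGCGCAT was higher in Oct4 than in Sox2 by a log2 difference of 1.80 and than in Nanog by 1.92, and it had been chosen as the highest 8-mer in Oct4, which favours differences in this direction. Repeated listing of few sequences is argued against, since the log2 fold over controls was still 1.97 with each sequence counted once, as are a few loci, since the 10 most frequent contexts of the motif held 7.86% of its Oct4 reads. GC and CpG content as the whole cause is also argued against, as the log2 fold among 8-mers of the same content was 2.03 (SE 0.079) against 2.10 without that step, which took Oct4 calls from 53 to 17. A candidate explanation is binding of Oct4 or another POU protein to the palindrome as a pair, which was not tested, and Oct4 has 1 library. An antibody preference for other proteins was not tested either.

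The 42 contigs set aside, 5712 bases in all, were read in some libraries whatever the target, at 321 RPM in Oct4, 231 and 1031 in Suz12 replicates 1 and 2, 371 in H3K79me2 replicate 2, and 247 and 174 in H3K36me3 replicates 1 and 2. The contigs were built from Suz12 reads and picked by their Oct4, H3K79me2 replicate 2 and H3K36me3 replicate 2 reads, so the levels in Suz12 replicate 1 and H3K36me3 replicate 1 are the ones free of that choice. Mouse sequence in many copies is argued against by the input libraries, which held 0.419 and 23.6 RPM, a ratio of 56.3. Oct4 and Suz12 replicate 2 reads kept nearly 1 ratio over the contigs (chi-square per degree of freedom 1.17, 41 degrees of freedom), which is consistent with another DNA source in some libraries, though the choice by Oct4 reads narrows that ratio. The source was not identified.

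Other differences between factors, as log2 values over controls, were 1.25 at the Nrf1 motif for Oct4 minus Sox2 (adjusted p 1.0e-05). For Oct4 minus Nanog they were 1.02 at the octamer (adjusted p 7.0e-08), 1.68 at the composite motif (adjusted p 7.0e-08) and 1.24 at the CTCF motif (adjusted p 7.0e-08). For Nanog minus Sox2 the composite motif gave -1.20 (adjusted p 1.3e-06).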

How the results depend on the processing

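The tests with DESeq2, TMM and median scaling, no low-count filter, high input left out, a fold threshold inside the test, 2 groups only, the replicate block and single libraries left out were planned, and the other tests were chosen after the data had been seen. All 195 values of motif results kept their direction and side of the threshold under every alternative run for them. Of 236 8-mer counts 204, and of 327 contig counts 264, stayed within 1.5 times the main count. No value that had passed its test changed direction, whereas the H3K36me3 ratios on contigs with Suz12 reads, which had not, went to either side of 1. The cause of the changes below was not tested except where fewer contigs or libraries entered by construction. On simulated Nanog contigs, with rises and losses in equal number, a log2 change of 2 was recovered in 29% for Sox2 and 4.5% for Oct4, and a change of 4 in 85% and 63.5%. Depth was not varied there, so how far it limits the contig counts was not tested. The planned pseudocount, 2 kb windows, 10 kb distance, region merging and promoter lists were not run, since reads were not placed on a genome, and a low-count filter removes no 8-mer.

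With DESeq2 the Nanog contigs called were 700 in Oct4, 536 in Sox2, 244 in Tcf3 and 185 in all 3, and with 1 mean dispersion 801, 592, 251 and 189. With either, H3K4me3 contigs called in Suz12, H3K79me2 and H3K36me3 and Suz12 contigs called in H3K4me3 numbered 0, with 0, 0, 1 and 0 at an unadjusted p under 0.05 and the same fold. With TMM the 8-mers called were 31 in Oct4, 24 in Sox2 and 1 in H3K79me2. Without the low-count filter, Nanog contigs were 3184 in Oct4 and 2326 in Sox2, Oct4 contigs 1714 in Sox2 and 1504 in Nanog, and H3K4me3 contigs 2 in Suz12 and 918 in H3K79me2. With the fold threshold inside edgeR's test, 8-mers were 6 in Oct4 and 0 in Sox2, Nanog, Suz12, H3K79me2 and H3K36me3 (11, 1, 162, 0 and 8 at an unadjusted p under 0.05), and H3K4me3 contigs were 0 in Suz12 (100 unadjusted) and 344 in H3K36me3. With 2 groups only, edgeR called 0 H3K4me3 contigs in Suz12, with 94 unadjusted.

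With each sequence counted once, edgeR's 8-mer calls were 28 in Sox2 and 0 in Nanog, H3K79me2 and H3K36me3 (0, 2 and 0 at an unadjusted p under 0.05), and contig calls in Suz12 were 5 for Nanog and 3 for H3K4me3 contigs. With all 19 libraries as labelled, 8-mers were 17 in Oct4, 0 in Suz12 (146 unadjusted), 3485 in H3K79me2 and 4 in H3K36me3, Nanog contigs in Suz12 were 10, and H3K4me3 contigs were 0 in Suz12 (57 unadjusted), 154 in H3K79me2 and 2 in H3K36me3. SINE B1 in H3K79me2 was then 0.45 (adjusted p 0.24), past the threshold no longer, and major satellite in H3K79me2 was -2.01 (main -3.58). With each sequence counted once, major satellite was -2.60 in H3K79me2 and -1.22 in H3K4me3 (main -1.83), and minor satellite in H3K36me3 was -1.04 (main -1.99). With the Tcf3 runs separate, Nanog contigs in Suz12 were 10. With the H3K36me3 libraries summed as 1 sample, H3K4me3 contigs called by edgeR were 261 in H3K36me3 and 0 in Suz12 (95 unadjusted). Within GC and CpG classes, edgeR called 17 8-mers in Oct4, 4 in Sox2, 0 in Nanog and Suz12 (0 unadjusted), 166 in H3K4me3, 14 in H3K79me2 and 1 for Tcf3 against the mean. With contigs of at least 60 bases, which are fewer, Nanog contigs were 890, 899, 743 and 654 in Oct4, Sox2, Tcf3 and all 3, Oct4 contigs 313, 292 and 213 in Sox2, Nanog and Tcf3, and Suz12 contigs 3 in H3K4me3. With the low-count filter first used, on the fitted libraries, Nanog contigs were 975, 947 and 754 and H3K4me3 contigs in H3K79me2 731. With the first adapter sequence alone, 8-mers were 52 in Oct4, 495 in Suz12 and 6991 in H3K4me3.

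For H3K4me3 contigs with Suz12 reads, the H3K79me2 ratio was 0.554 with at least 3 Suz12 reads, 0.230 with at least 10, 0.518 with any number of input reads, 0.285 with no CpG matching and 0.245 with each sequence counted once. The ratio of H3K36me3 replicate 1 was 0.839 with at least 10 Suz12 reads, 1.83 with any input and 0.854 with no CpG matching, and that of replicate 2 was 1.87 (95% counting interval 1.75 to 1.99) and 0.822 (0.734 to 0.918) in the last pair. On the 5 contigs called for Suz12 the ratios were 0.0417 (95% counting interval 0.00106 to 0.232), 1.49 (0.181 to 5.40) and 0.560 (0.116 to 1.64), from 1, 2 and 3 reads, and on 7 called with the first low-count filter the H3K79me2 ratio was 0.0188 (0.000476 to 0.105), from 1 read.

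Leaving out 1 library gave 29 (input replicate 1) to 111 (input replicate 2) 8-mers in Oct4, 32 to 168 in Sox2 and 1 to 8 in Nanog for the same libraries, and 49 (Suz12 replicate 2) to 1091 (Suz12 replicate 1) in Suz12. Nanog contigs ranged from 751 (input replicate 2) to 1179 (Suz12 replicate 1) in Tcf3, from 0 to 20 (Suz12 replicate 1) in Suz12, and from 554 (input replicate 2) to 1027 (Suz12 replicate 1) in all 3, with 587 and 560 without Sox2 replicates 1 and 2. H3K4me3 contigs in H3K79me2 ranged from 208 (input replicate 2) to 2036, with 413 without input replicate 1. In H3K36me3 they ranged from 130 (input replicate 2) to 637, with 143 and 204 without H3K36me3 replicates 2 and 1 and 206 without input replicate 1. In Suz12 they ranged from 0 to 8 (Suz12 replicate 1), with 1 without input replicate 1. The edgeR counts of 0 there came without Suz12 replicate 2, H3K36me3 replicate 1, H3K36me3 replicate 2 and input replicate 2, with 29, 96, 100 and 55 at an unadjusted p under 0.05. With Suz12 replicate 2 alone or replicate 1 alone, the H3K79me2 ratio was 0.307 or 0.065 (0.00165 to 0.362, from 1 read), that of H3K36me3 replicate 1 was 1.06 or 0.384 (0.00972 to 2.14, from 1 read) and that of replicate 2 was 0.987 or 0.180 (0.0218 to 0.649, from 2 reads). A group left with 1 library is assumed to vary like the others.

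With the replicate number as a block, in Oct4, Sox2, Nanog and input libraries alone, 8-mers called were 57 in Oct4, 52 in Sox2 and 3 in Nanog, Nanog contigs 1271 in Oct4 and 1121 in Sox2, and Oct4 contigs 813 in Sox2 and 794 in Nanog. The same libraries without the block gave 52, 51, 3, 1522, 1484, 813 and 793, so no count moved by over 1.5 times. The numbers do not pair the samples by their values: replicate 1 minus 2 over 8-mers correlated at 0.135 between Sox2 and Nanog, -0.337 between Sox2 and input and -0.121 between Nanog and input. Tcf3 was left out, since its merged runs carry both numbers.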

Other observations

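Some contigs with a motif carried more reads of factors other than the one that built them. These values were looked at only after the contigs had been built, and the differences were not tested. Nanog contigs with the composite motif, 21 in number, had 2.63 times the Oct4 reads of the other Nanog contigs and 2.82 and 2.89 times the reads of Sox2 replicates 1 and 2. Nanog contigs with the octamer, 106 in number, had 2.86 times the Oct4 reads, 2.41 and 2.42 times the Sox2 reads and 2.78 times the Tcf3 reads. Tcf3 contigs with the octamer, 35 in number, had 2.91 times the Oct4 reads and 2.15 and 2.10 times the reads of Nanog replicates 1 and 2. Input replicates 1 and 2 had 1.63 and 1.59 times as many reads on the Nanog contigs with the octamer as on the others, 1.45 and 1.27 times as many on those with the composite motif, from 8 reads each, and 0.787 and 0.932 times as many on the Tcf3 contigs with the octamer.

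For major satellite, Tcf3 gave a log2 share over input of 0.29 (SE 0.16, adjusted p 0.15), which did not pass the test.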
